A study of Oryza sativa with 4 samples.

How the data were processed

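RNA was extracted from rice seedlings and made into libraries with a kit for Illumina sequencing, per the labels' protocols. The 4 samples are 2 wild type replicates of the line SN9816 and 2 replicates of bta1-1, grouped by their labels. The design text calls them biological replicates, and the labels used here do not say whether equal replicate numbers mark a shared tray, day or batch.

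Read counts per gene were deposited by the authors as whole numbers without normalization. Read counts differed in total between the libraries, from 15093108 to 20334851. FPKM values for the same genes and libraries were deposited in a second table, normalized by the authors for gene length and library size. Dividing counts by FPKM gave a gene length that was whole within 0.01 base in 100% of 123342 values and the same in each library, so both tables come from the same counts. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the rice build IRGSP-1.0, with no role or order. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and reads of near-identical copies, histones above all, may have been split or dropped.

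The count table held 91960 features, of which 37830 carry a rice locus identifier with the chromosome in it. These took 99.28% to 99.39% of the counted reads in each library. No feature without a gene identifier was included. The replicates of a group were not copies of one library, since a chi-square test of their counts gave 35.7 (wild type) and 49.4 (bta1-1) per degree of freedom.

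Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit, group as the 1 term, two-sided, Benjamini-Hochberg adjustment over the 24396 genes kept). A gene is called at an adjusted p under 0.05 with no fold threshold. Standard errors are the log2 fold change divided by the square root of its F statistic, and CPM are TMM-scaled. The biological coefficient of variation was 0.242. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 22 lists with at least 3 tested members, and again with an estimated correlation. Of the 6 lists called with the preset correlation, 0 were called with the estimated one. With an estimated correlation, camera uses the residual degrees of freedom of the 4 libraries, which are few. The strigolactone list, at an estimated correlation of -0.2, went from camera p = 0.0213 to 0.143. That setting could hardly call any list here, so its adjusted p cannot decide against one. Fisher's exact test compared called members with all genes tested per direction.

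Depth and replication set what could be seen. In counts simulated for 24396 genes from the means and library sizes of this comparison, with 200 changed genes, 18% of 2-fold and 65% of 4-fold changes were recovered, and 9 unchanged genes were called. Fewer genes were changed there than the 1319 called in the data. The adjustment was stricter for that reason, and the recovery in the data may differ. Genes with a few reads, such as PIN5b, RR7 and GH3-8, have wide errors at this depth and replication.

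The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. For LAZY1 and the 7 lists of auxin, tiller angle, strigolactone and clock genes, 95 loci were set at the same time. For the others the name patterns found no descriptions to match, and 191 member loci were added after the files were opened and before fold changes were computed, when the reads of LAZY1 and of the most abundant genes had been seen. Lists of SAUR genes, cytosolic ribosomal proteins, and peroxidases with glutathione transferases were not resolved to loci and were left out. Names came from published locus identifiers, checked against a RefSeq gene table of another rice assembly (ASM3414082v1) by symbol, chromosome and approximate position, within 4 Mb. Of 286 listed pairs 216 matched, 4 were contradicted and dropped, and 66 symbols were not in that table. The histone loci, most light-harvesting genes, IAA27, ARF11, DLT, GA2ox3 and PR1a are among the 66, and their names rest on the locus identifier alone.

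Genes were named by a rule. It takes LAZY1, the 8 genes higher and the 8 lower with the smallest p among called genes that carry a name matched in the RefSeq table (in effect list members, since that table holds no rice locus identifiers of this kind), change at least 2-fold and do not overlap between groups. It adds up to 3 called members per list or, without any, the member with the smallest p, the called members of the tiller angle and auxin lists, and up to 5 genes per direction detected in one group alone. The names CYCB1-3, MCM3, EXPB7, GI, PRR95, PRR1, LHY, NAS1, NAS2, YSL15, LSI1, the uncalled histone loci and those of untested genes were chosen after their values were seen.

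Positions along chromosomes were taken from the order of locus numbers among 23249 tested genes. Neighbouring pairs of genes were compared with 1000 shuffles of the gene order, and segments are windows of 50 tested genes with at least 5 genes detected in one line alone, trimmed to the outermost of these.

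Alternatives to the main settings were RLE and upper-quartile normalization, no count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, a test against a 1.5-fold change, each library left out in turn, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, and log2(FPKM + 1) for all genes. With a library left out, the lone sample of its group is assumed to vary like the other group. Lists were also tested with fry, with the block, and on FPKM. A crossed pairing of the replicates, a fit without the genes of the segments, and counts of list members per setting were added after seeing the data.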

Results

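Transcripts were counted by RNA sequencing in seedling samples of rice (Oryza sativa, japonica) at 7 days of age, raised with 14 h of light and 10 h of dark. The 4 libraries form 2 groups of 2 biological replicates, the wild type line SN9816 and the mutant bta1-1. The background of bta1-1 is not given in the sources used here, so differences between the groups can come from the mutation or from other differences between the lines. BTA1 is known as an allele of LAZY1, a gene that promotes shoot gravitropism and keeps rice tillers upright. Wild type libraries 1 and 2 held 20334851 and 15093108 counted reads, and bta1-1 libraries 1 and 2 held 17332067 and 17365812. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.9693 within wild type and 0.9704 within bta1-1, and it ranged from 0.8928 to 0.928 between the groups. The series title puts the question as how BTA1 acts on tiller angle and gravitropism through auxin, and the design offers 1 comparison for it, bta1-1 against wild type.

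LAZY1 (OS11G0490600) itself fell 7.65-fold in bta1-1, from 34.5 ± 3.31 to 4.51 ± 0.441 CPM (SD, n = 2 per group). In bta1-1, 13 of 16 tested histone genes (H3 and H4 loci only), 4 of 7 replication genes (MCM genes and PCNA only) and 4 of 5 mitotic genes were higher. Of 15 drought and abscisic acid genes 4 were lower, among them RAB16A by 30.2-fold, and 1 was higher, DREB1B by 4.28-fold. As lists, none of these was called by camera with an estimated correlation (adjusted p = 0.645 for the first 3 and 0.694 for the drought list). With 4 libraries that setting has too few degrees of freedom to decide. The median of the drought list turned from -0.73 to 0.16 without wild type library 1. Few auxin genes passed the test: 2 Aux/IAA repressors and 1 auxin response factor were higher, and no auxin carrier was called. Expansins EXPA29, EXPA6 and EXPA4 rose, and the clock gene LUX and the gibberellin oxidase GA2ox3 fell.

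LAZY1 had 767 and 461 reads in wild type libraries 1 and 2 against 70 and 89 in bta1-1 libraries 1 and 2, a log2 fold change of -2.93 (SE 0.26, adjusted p = 0.000445, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, used for all genes here). The transcript was therefore reduced and still detected in both mutant libraries. On log2(FPKM + 1) over all genes with any value, it had adjusted p = 0.0733 by limma. Of 24396 genes tested, 675 were higher and 644 lower in bta1-1, together 5.4% of the genes. The number higher was 401 without wild type library 2 and 1202 without bta1-1 library 1. P-values set each difference against a spread estimated from these samples and moderated across genes. They do not measure variation between lines, and with 2 per group an uncalled gene is not shown to be unchanged.

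**Figure D1:**
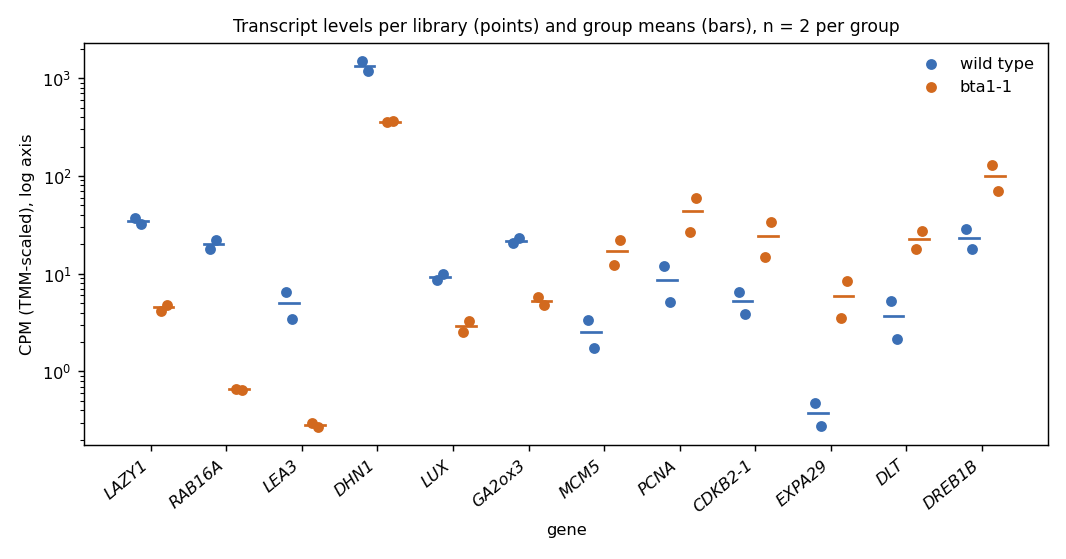
Transcript level (TMM-scaled CPM, log axis) of 12 named genes in each of the 4 libraries, wild type in blue and bta1-1 in orange, with horizontal bars at the mean of each group (n = 2). LAZY1 lies near 34.5 CPM in wild type and 4.51 CPM in bta1-1, and for each gene shown the libraries of the groups do not overlap. For most of these genes the rule for naming required this separation.

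Of 16 tested histone loci, 13 were higher and none lower in bta1-1 (14 higher when adjusted over the list alone), with a median log2 fold change of 2.00. The list held loci of H3 and H4 only, so other histone families were not covered. Called H4 loci, 9 of 10 tested, rose by log2 1.27 to 2.74, and called H3.2 loci, 4 of 5 tested, by 2.28 to 2.95. The replacement histone H3.3, whose expression is not tied to DNA replication, had a log2 fold change of -0.25 at its 1 tested locus and was not called, and neither were H3.2 locus OS04G0450800 at 0.02 and H4 locus OS10G0539500 at 0.91. H4 locus OS02G0684500 went from 19 ± 5.3 to 122 ± 50.1 CPM (SD, n = 2), and H3.2 locus OS06G0159450 from 8.07 ± 4.70 to 63.2 ± 29.0 CPM. Histone loci are near-identical copies, so the split of reads among them is uncertain. By limma on the deposited FPKM, 4 histone loci were called on log2(FPKM + 1), 2 on log2(FPKM + 0.1) and 0 on log2(FPKM + 1) for all genes, with medians of 1.96, 2.03 and 1.74. The list was higher by camera with a preset correlation (adjusted p = 8.1e-10), and with an estimated correlation the adjusted p = 0.645.

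Of 7 tested replication genes, 4 were higher (7 when adjusted over the list alone). They were MCM5, MCM4 and MCM3, subunits of the replicative helicase, and PCNA, the sliding clamp. The list held only subunits of that helicase and PCNA. MCM5 went from 2.53 ± 1.11 to 17.2 ± 6.85 CPM (SD, n = 2; log2 fold change 2.74, SE 0.43, adjusted p = 0.0102), and PCNA rose 4.98-fold. Of 5 tested mitotic genes, 4 were higher (5 when adjusted over the list alone): the B-type cyclins CYCB2-2, CYCB2-1 and CYCB1-3 and the kinase CDKB2-1, which drive entry into mitosis, by log2 2.1 to 2.61. Camera gave adjusted p = 1.76e-05 for replication and 0.000214 for mitosis, and with an estimated correlation adjusted p = 0.645 for both. Within the groups these lists also differed: the replication median was 1.23 (log2) higher in wild type library 1 than 2 and 1.1 higher in bta1-1 library 2 than 1, against 0.71 and 1.06 for the mitotic list and 0.44 and 0.73 for the histones. Without wild type library 2, 0 mitotic and 4 replication members were called, with CYCB2-2, CYCB2-1 and CDKB2-1 at adjusted p = 0.0556, 0.0706 and 0.0508. Without bta1-1 library 2, 2 members of each list were called, with MCM4 at adjusted p = 0.0509 and CYCB2-1 at 0.0517, while 7 replication members were called without wild type library 1 or without bta1-1 library 1. On the 3 FPKM settings 0 replication and 0 mitotic members were called, with medians of 1.91, 2.37 and 1.91 for replication and 1.75, 2.17 and 1.58 for mitosis. The study is known to have reported nucleosome and chromatin assembly genes from these samples, so the histone, replication and mitotic lists are not independent evidence of their direction.

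Of 15 tested genes of the water-deficit and abscisic acid response, 4 were lower, 1 was higher and 10 were not called (7 lower and 2 higher when adjusted over the list alone). RAB16A, a dehydrin induced by abscisic acid, fell from 20 ± 3 to 0.654 ± 0.00677 CPM (SD, n = 2; log2 fold change -4.92, SE 0.35, adjusted p = 0.000179). LEA3, a late embryogenesis abundant protein, fell 17.2-fold, and the dehydrin RAB16B fell 7.54-fold. The abundant dehydrin DHN1 fell from 1350 ± 220 to 359 ± 4.15 CPM. Opposite to these, DREB1B, a transcription factor of the cold response, rose 4.28-fold from 23.2 ± 7.90 to 99.9 ± 41.6 CPM. The list was lower by camera (adjusted p = 0.00995), and with an estimated correlation the adjusted p = 0.694. Without wild type library 1 the list had adjusted p = 0.128 and a median log2 fold change of 0.16 in place of -0.73, while 4 members were still called lower. On log2(FPKM + 1) and log2(FPKM + 0.1) 3 members were called lower and 0 higher, and 0 in either direction on log2(FPKM + 1) for all genes. Drought tolerance is among the subjects the study is known to have reported, so this list is not independent evidence either.

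Of 9 tested clock genes, 1 was lower, LUX, and 3 when adjusted over the list alone. The list was lower by camera (adjusted p = 0.00385), and with an estimated correlation the adjusted p = 0.645. LUX, part of the evening complex of the clock, fell from 9.27 ± 1.01 to 2.88 ± 0.517 CPM (SD, n = 2; log2 fold change -1.68, adjusted p = 0.0272), with adjusted p = 0.0885 without wild type library 2 and 0.055 without bta1-1 library 1. The uncalled members GI, PRR95 and PRR1 had log2 fold changes of -0.93, -0.95 and -0.88 (adjusted p = 0.192, 0.0822 and 0.0691), and the morning gene LHY had 0.57. Defence genes were also lower as a list (adjusted p = 0.0257, and adjusted p = 0.645 with an estimated correlation), although 0 of 7 tested members were called, and 0 when adjusted over the list alone. Their median log2 fold change was -0.74, PR1a had -2.14 (adjusted p = 0.127), and the list had adjusted p = 0.104 without wild type library 1 and 0.142 on log2(FPKM + 1).

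**Figure D2:**
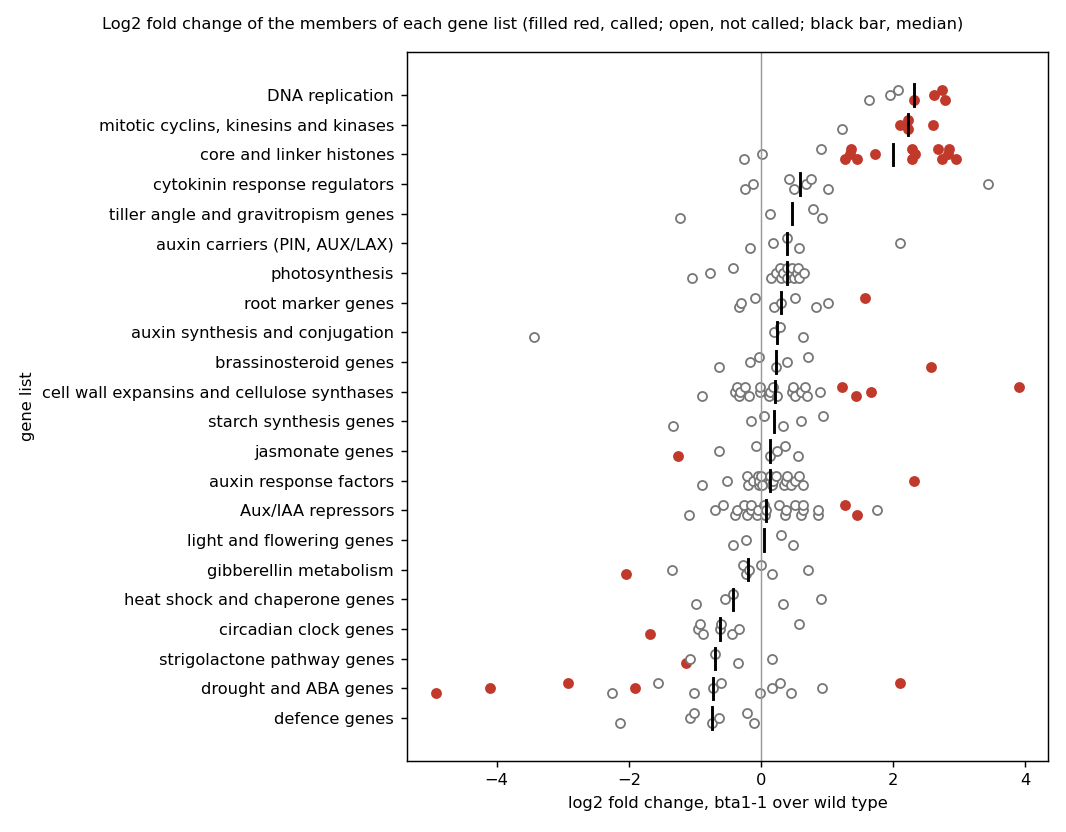
Log2 fold change of bta1-1 over wild type (horizontal axis) for each tested member of the 22 gene lists with at least 3 tested members (vertical axis), filled red where called and open where not, with a black bar at the list median. Replication, mitotic and histone genes lie to the right with medians of 2.32, 2.22 and 2.00, and drought and ABA genes spread from -4.92 to 2.1.

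Auxin genes, the stated interest of the study, changed at few members. Of 26 tested Aux/IAA repressors of auxin signalling, 2 were higher (2 when adjusted over the list alone): IAA12 rose 2.42-fold and IAA27 2.74-fold. Of 23 tested auxin response factors, 1 was higher (1 when adjusted over the list alone), ARF11, from 0.915 ± 0.405 to 4.68 ± 1.19 CPM (SD, n = 2; adjusted p = 0.0295). Each of these 3 calls was lost when 1 of several libraries was left out. Without wild type library 1, IAA27 and IAA12 had adjusted p = 0.145 and 0.0506, without wild type library 2 the values were 0.108 and 0.165, and without bta1-1 library 2 they were 0.2 and 0.148. ARF11 had adjusted p = 0.096 without wild type library 2 and 0.0615 without bta1-1 library 2. Among 5 tested auxin carriers 0 were called, and 0 when adjusted over the list alone, with PIN5b at a log2 fold change of 2.1 (adjusted p = 0.112) on 4 and 3 reads against 12 and 19. The carriers PIN1a, PIN2, PIN3b, PIN5c, PIN8 and PIN9 had too few reads to be tested. Of 4 tested genes of auxin synthesis and conjugation 0 were called and 1 was lower when adjusted over the list alone, GH3-8 with a log2 fold change of -3.43 (adjusted p = 0.0854). That list had a median of 0.24 and a mean of -0.57. By camera these lists had adjusted p = 0.268 for Aux/IAA repressors, 0.347 for response factors, 0.205 for carriers and 0.96 for synthesis and conjugation. The study named auxin transport and signalling itself, so none of these lists is independent evidence.

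Other genes known to set tiller angle or branching gave 1 call. Of 4 tested tiller angle and gravitropism genes 0 were called, while 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.637). The member with the smallest p was IPA1, a regulator of plant architecture, at a log2 fold change of 0.92 (adjusted p = 0.191). In the strigolactone pathway 1 of 5 tested genes was lower, and 3 when adjusted over the list alone (camera adjusted p = 0.0586, and 0.0383 on log2(FPKM + 1)). The list median was -0.7, and -0.63 without wild type library 2. The called gene was D17, which encodes a carotenoid cleavage enzyme of strigolactone synthesis and fell from 39.2 ± 11.4 to 17.8 ± 1.64 CPM (SD, n = 2; adjusted p = 0.0444). Its adjusted p was 0.216 without wild type library 1 and 0.104 without bta1-1 library 2.

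Of 24 tested cell wall genes, 4 were higher and none lower (4 higher and 1 lower when adjusted over the list alone). The 4 were among 15 tested expansins, which loosen walls during growth, and 0 of 9 tested cellulose synthases were called, a difference between the families that was not tested. EXPA29 rose from 0.380 ± 0.142 to 5.96 ± 3.43 CPM (SD, n = 2; log2 fold change 3.91, SE 0.61, adjusted p = 0.0101), EXPB7 3.18-fold, EXPA6 2.71-fold and EXPA4 2.32-fold. By Fisher's exact test the list held more higher calls than other genes (adjusted p = 0.035), and by camera it had adjusted p = 0.0679. Without a library in turn, the Fisher adjusted p was 0.865 (wild type library 1), 1 (wild type library 2), 0.21 (bta1-1 library 1) and 0.607 (bta1-1 library 2), and the camera values in the same order were 0.00818, 0.614, 0.00276 and 0.781. EXPA4 had adjusted p = 0.114, 0.0717 and 0.128 without wild type library 1, wild type library 2 and bta1-1 library 2, and EXPA6 had 0.0512 without wild type library 2.

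Growth hormone lists held scattered changes. GA2ox3 (OS01G0757200), an enzyme that inactivates gibberellins, fell from 21.7 ± 1.76 to 5.26 ± 0.699 CPM (SD, n = 2; log2 fold change -2.05, adjusted p = 0.00424) as the 1 called of 8 tested gibberellin genes, with 2 lower when adjusted over the list alone (camera adjusted p = 0.318). DLT (OS06G0127800), a GRAS protein of brassinosteroid signalling, rose 5.96-fold (adjusted p = 0.0136) as the 1 called of 7 brassinosteroid genes, and 1 when adjusted over the list alone (camera adjusted p = 0.334). JAZ8, a repressor of jasmonate signalling, fell 2.37-fold as the 1 called of 7 jasmonate genes, and 1 when adjusted over the list alone. JAZ8 had adjusted p = 0.158 without wild type library 1 and 0.0886 without bta1-1 library 2. The jasmonate list had a median of 0.14, a mean of -0.09 and a camera adjusted p of 0.96. Of 8 cytokinin response regulators 0 were called, and 0 when adjusted over the list alone. Their median was 0.59 (camera adjusted p = 0.0586, and 0.02 with the replicate number as a block), and 0.93 without wild type library 1. RR7 had 0 and 4 reads in wild type and 15 and 33 in bta1-1 (adjusted p = 0.0914, 0.0245 without wild type library 2 and 0.0381 without bta1-1 library 1).

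Photosynthesis genes were not called, 0 of 17 tested and 0 when adjusted over the list alone, with a median log2 fold change of 0.39 (camera adjusted p = 0.314). The list had adjusted p = 9.81e-05 without bta1-1 library 2, and its median differed by -0.49 (log2) from wild type library 2 to 1 and by -0.92 from bta1-1 library 1 to 2. RBCS5, a small subunit of Rubisco, stood at 824 and 1520 CPM in the wild type libraries and at 862 and 284 CPM in those of bta1-1, with adjusted p = 0.386, and 0.0166 without bta1-1 library 1. Among root marker genes, 1 of 9 tested was higher, and 1 when adjusted over the list alone (camera adjusted p = 0.314): NAS3, a nicotianamine synthase, rose 2.97-fold, with adjusted p = 0.187 without wild type library 1 and 0.0954 without bta1-1 library 2. Uncalled members ranged widely in level, with NAS1 and NAS2 at 432 and 393 CPM in wild type, YSL15 at 21.7 CPM and LSI1 at 7.7 CPM, while NRT2.2 and AMT1-2 had 0 reads in each library.

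No member was called, over all genes or when adjusted over the list alone, in the lists of heat shock genes (5 tested), light and flowering genes (4), starch synthesis genes (6) and seed storage genes (2). Their members with the smallest p were HSP16.9A at a log2 fold change of 0.91, PHYB at -0.42, SSI at 0.94 and RAMY1A at 1.43. RAMY1A, an amylase of germination, had 52 reads in bta1-1 library 2 and 7 to 12 in the others, so that its log2 fold change was -0.48 without bta1-1 library 2 and its adjusted p = 0.0441 without bta1-1 library 1. Camera gave adjusted p = 0.728 for heat shock, 0.746 for starch, and 0.96 for light and flowering, whose median and mean were 0.04 while the test pointed lower. The shoot meristem genes OSH1, OSH15 and MOC1 had at most 7 reads in any library and were not tested.

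A further group of genes was read in one line and almost not in the other. With at least 20 reads in each library of one group and at most 3 in each library of the other, 118 genes were detected in wild type alone and 52 in bta1-1 alone. OS01G0728400 had 1726 and 993 reads in wild type against 1 and 2 in bta1-1, and OS10G0365800 had 745 and 509 against 1 and 1. In the opposite direction OS11G0635500 had 2 and 1 reads against 681 and 990, and OS02G0807750 had 2 and 2 against 429 and 452. The sources used here pair none of these with a name. Chromosome 10 carried 41 of the 141 such genes that have a chromosome in their identifier, chromosome 1 carried 24, chromosome 12 carried 20 and chromosome 7 carried 1. Chromosome 10 also had the highest share of called genes, 10% of 1235 tested, and chromosome 12 had 8.6%, against 3.7% to 5.8% on the others.

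**Figure D3:**
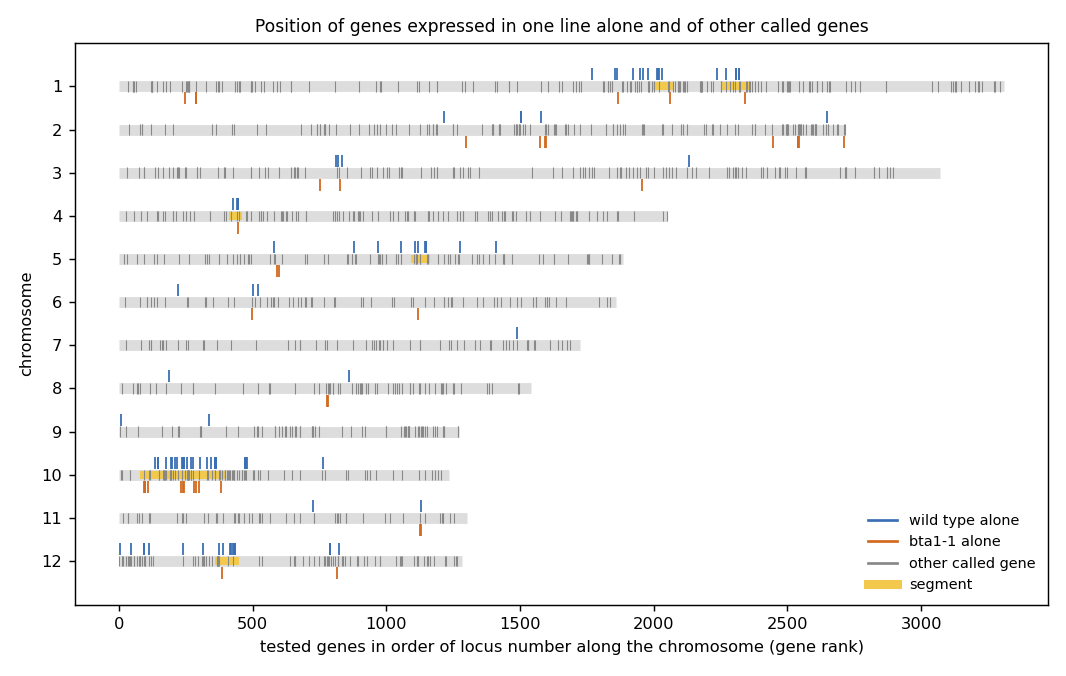
Tested genes of the 12 rice chromosomes in order of locus number (horizontal axis, gene rank), with genes detected in wild type alone as blue ticks above, genes detected in bta1-1 alone as orange ticks below, other called genes as grey ticks, and the 6 segments dense in the first kinds in yellow. Chromosome 10 carries 41 such genes, 36 of them in its segment of 287 tested genes.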

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

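The crossed pairing and the fit without segment genes were chosen after seeing the data, and the other alternatives before. Of 1020 recomputed values 807 stayed on the same side of their threshold, or within 1.5 times for counts, and no gene called in bta1-1 against wild type was called in the opposite direction under any alternative. Genes higher and lower (675 and 644) were 1582 and 1322 with all genes of any count, 355 and 387 against a 1.5-fold change, 156 and 280 on log2(FPKM + 1), 125 and 239 on log2(FPKM + 0.1), and 2 and 9 on log2(FPKM + 1) for all genes. Leaving out each library gave 401 to 1202 genes higher and 482 to 854 lower. Without the segment genes 603 were higher and 510 lower. RLE and upper-quartile scaling moved the median of all genes to -0.021 and 0.021 from -0.012, and DESeq2 called 1000 and 873 genes.

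LAZY1 kept its direction, from -3.03 to -2.54, and its call except on log2(FPKM + 1) for all genes, where it was -2.54 with adjusted p = 0.0733. Called named genes (37) were 18, 17 and 2 on the 3 FPKM settings and 28 to 36 without a library. Called lists (6) were 6 on log2(FPKM + 1), 6 with RLE size factors and 7 with the replicate number as a block. They were 0 with an estimated correlation and 0 by the directional test of fry, where the smallest adjusted p was 0.193. The mixed test of fry, which takes changes in either direction together, called 7. The histone, replication and mitotic lists were not among them. With each library left out in turn, these lists stayed higher in bta1-1. Their median log2 fold changes were then 1.6 to 2.17 (histones), 1.66 to 3.09 (replication) and 1.54 to 2.63 (mitosis). Lists with more called members than other genes (5) were 2 to 4 without a library, and the cause was not tested.

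Tests that turned direction belonged to results that were not called, while the called drought list had its median turn from -0.73 to 0.16 without wild type library 1. RAMY1A ranged from -0.48 without bta1-1 library 2 to 2.21 without bta1-1 library 1. Adjusted p in the opposite direction was 0.481 and 0.964 for auxin synthesis without wild type library 1 and 2, and 0.987 for heat shock genes on FPKM. For jasmonate genes it was 0.943 by fry, 0.299 without wild type library 2 and 0.827 without bta1-1 library 1. Light and flowering genes had 0.964 without wild type library 2 and 0.781 without bta1-1 library 2, photosynthesis genes 0.858 without wild type library 1 and 0.2 without bta1-1 library 1, and tiller angle genes 0.751 without wild type library 1. Over all libraries left out, adjusted p in either direction ranged from 0.714 to 0.964 for light and flowering, 9.81e-05 to 0.858 for photosynthesis and 0.614 to 0.827 for tiller angle. The cause was not tested.

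With the replicate number as a block, 359 genes were higher and 415 lower, 24 of the named genes were called, 9 histone, 1 replication and 0 mitotic members were called higher and 4 drought members lower, 2 lists held more called members than other genes, and LAZY1 was at -2.93 with its call kept. The numbers are not known to pair the samples: across genes the difference of replicate 1 and 2 in wild type correlated at -0.416 with that in bta1-1, over 2 pairs. With the crossed pairing as a block, 1972 genes were higher and 1772 lower. Given the negative correlation, that block takes up shared variation, so the rise follows from how the pairs were formed. A block of either kind also leaves fewer degrees of freedom, which by itself can lose calls.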

Other observations

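The tests of chromosome position, of gene models, of OSH1 and OSH15 reads and of LHY were chosen after the result was seen. Gene models that the deposited table numbers apart from annotated genes were read in one line alone more often than other features. The counts were 27 of 750 tested (3.6%) against 143 of 23646 (0.6%, Fisher's exact test p = 2.54e-12). If these models were built from reads of these libraries, they were selected by expression here and the other features were not. The p-value would then not compare like sets. Genes read in one line alone were next to each other more often than in shuffled gene orders, and so were the other called genes, with 95 neighbouring pairs among 1102 genes against a median of 52 and at most 78 in 1000 shuffles (permutation p = 0.001, the smallest they can give). The segments on chromosomes 1 (2 segments), 4, 5, 10 and 12 together held 532 tested genes and 66 of the 141 genes read in one line alone, 51 in wild type and 15 in bta1-1. A window of 5 such genes also occurred in shuffled orders, so the segments with 5 are weaker than that of chromosome 10 with 36 and that of chromosome 12 with 9. The 1 list member in a segment was the uncalled GH3-1.

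Genes expressed in one line and not the other formed 28 neighbouring pairs, against a median of 1 and at most 5 in 1000 shuffles of the gene order. Redrawing them among the 1243 genes called or read in one line alone gave at most 8 pairs. This argues against regulation by BTA1 of genes placed independently of each other over the genome as the sole cause. Joint regulation of neighbouring genes would also give pairs and was not tested. Deletion of whole segments in bta1-1 is argued against on chromosomes 1, 5, 10 and 12. There 82.3% of genes expressed in wild type (348 of 423, the lowest exact 95% limit of a segment being 63.4%) kept at least 20 reads in both bta1-1 libraries. On chromosome 4 41.7% were kept (5 of 12, 15.2% to 72.3%), an interval too wide to place the share, and 1 gene was read in bta1-1 alone. The reads of these genes argue against loss of that whole segment, while loss of parts of it stays open. It also stays open that the lines may differ in sequence in inherited chromosome blocks, which would alter detection against the reference or expression itself. The 28 pairs prompted this explanation and are no separate test of it. No variants were examined here, so this is a hypothesis, and smaller deletions remain open too.

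Of 28 replication, histone and mitotic genes 21 were called higher in bta1-1. None of the 3 lists was called by camera with an estimated correlation (adjusted p = 0.645), which cannot decide with 4 libraries. The median difference of the 28 genes was 2.18 (log2), and they also differed between libraries within both groups by a median of 0.87, a ratio of 2.51. The 200 other genes that differed most in the same way within both groups had a ratio of 0.16 (bootstrap 95% interval 0.11 to 0.25). The ratio was 0.18 when the genes were drawn, in a version added later, from those of at least 10 CPM. These genes were chosen by the within-group difference that divides the ratio, which lowers it in advance. The ratio therefore cannot decide whether a library difference is the sole cause. Of the 21 called members 0 lay in the chromosome segments, which hold 2.3% of tested genes with a locus number. Lying in these segments therefore does not account for the calls, and position elsewhere was not tested. More shoot meristem in the bta1-1 samples cannot be told apart from a change within the same cells, because OSH1 and OSH15 had 8 reads in the bta1-1 libraries together and 1 in wild type. The mutation itself, and other sequence differences between the lines, may underlie the pattern and were not tested.

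Among clock genes LUX alone was called lower, with adjusted p = 0.0885 without wild type library 2 and 0.055 without bta1-1 library 1, and the list had adjusted p = 0.645 with an estimated correlation. GI, PRR95 and PRR1 had negative log2 fold changes that were not called (adjusted p = 0.192, 0.0822 and 0.0691), and the morning gene LHY had 0.57 (SE 0.26, adjusted p = 0.304). Harvest at another time of day could give that combination of these picked genes. Of 9 tested members 8 were negative, those not named here from -0.62 to -0.33. Whether a fall across so many members goes with another harvest time was not tested. The LHY value is too imprecise to decide, the labels used here give no harvest time, and an effect of the mutation on the clock was not tested.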
